A study of Mus musculus with 12 samples.

How the data were processed

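Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse bone marrow-derived macrophages. Per the labels' protocols, bone marrow cells of female C57BL/6 mice, wild type (WT) or knockout for the long noncoding RNA lincRNA-EPS (KO), were grown for 9 days in medium with 20% L929 supplement and treated with lipopolysaccharide (LPS, a component of the bacterial outer membrane) at 100 ng/ml for 0, 2 or 6 h. Each transposition reaction used 50000 cells, and libraries were made with a modified Nextera kit and sequenced on a NextSeq. The 12 libraries fall into 6 groups of 2, by genotype and time. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

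The authors deposited 1 peak list per library. Per the submitters' processing notes, Bowtie2 2.1.0, Picard and MACS2 were used with the mm9 build. The treatment of duplicate reads, the correction for the Tn5 insertion offset and the MACS2 settings are not given in the sources used here. An uncorrected offset moves a peak border by a few bases and has little bearing on whether a peak is called, while duplicates kept in the lists would raise the peak values. Peaks were called on each library alone, as the deposited peak names show. The deposited lists hold, for each peak, a fold ratio of the summit over the local background, −log10 p-values and q-values, and a score that is 10 times the −log10 q. These are the authors' own values for each peak and their sizes were not compared between libraries as measures of accessibility. They served to describe, rank and filter peaks within a list and to recover coverage, as described with the depth. The lists cover 19 autosomes and the X chromosome. Inside the deposited lists of the 4 libraries that the labels place at 2 h, the peak names give 1 h. The groups follow the labels, and that conflict could not be settled here, so the time called 2 h may be 1 h.

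The 886143 peaks of the 12 lists were merged where they overlapped by at least 1 bp, which gave 115231 regions, and each region was scored as called or not called in each library. A region was gained with LPS when all 4 libraries of the later time called it and 0 of the 4 libraries at 0 h did, and lost in the opposite case. A region separated the genotypes when it was called in 6 of 6 libraries of one genotype and 0 of 6 of the other, or, within a time, in 2 of 2 and 0 of 2. Such counts were set against the other splits of the same libraries into groups of the same sizes. Peak numbers per library were compared by exact two-sided permutation tests, with time labels exchanged within genotype or genotype labels within time. A comparison of 2 libraries with 2 cannot give a two-sided p below 0.333, so counts within a time have no test. Regions were named by a rule fixed before the data were examined. It takes up to 5 per direction and comparison, those whose peaks have the highest mean percentile of −log10 q within the libraries that call them, and all of them where there are 10 or fewer. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

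The number of reads per library is not given in the sources used here. A relative depth was recovered from the deposited values, because the fold is the summit coverage plus 1 over the background plus 1 and the p is a Poisson probability of both. Solving these for a whole-number coverage matched the deposited p within 0.001 on the log10 scale for 100% of peaks. The lowest background in a library served as its background coverage, in reads. To reduce depth differences, the summit coverage of each called peak was thinned at random by the ratio of the lowest background coverage to that of its library, and a peak was kept where its thinned −log10 p was at least 4.28. Thinning matches background coverage and not read number or enrichment: median summit coverage over background at regions called in all 12 libraries was 9.43 ± 0.27 in WT and 10.16 ± 0.0083 in KO at 0 h (SD, n = 2). This setting was chosen after the data were examined. Presence in a list has no counting interval, and a region not called in a shallow library may be open below the calling limit.

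The counting of regions was tested on simulated calls with 200 changed regions among 107589. It recovered 79.5% of regions gained by 6 h, 77.5% of those lost by 6 h and 74.5% of those called in KO only. Of the regions it called, 111 of 270 gained, 91 of 246 lost and 2 of 151 KO-only regions lay outside the changed set. Those arose by chance from call rates equal in all libraries, and they are many beside the 146 regions lost by 6 h. Each rate was the region's share of calls over the real 12 libraries, so regions that differ by time entered at intermediate rates. That can raise the number called by chance, so these counts give no chance level for the 146. The simulated call rates set an expectation of 81.5%, 81.5% and 73.5%. Recovery of summit coverage was tested on 11656 simulated peaks and returned 100.0% of them.

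Alternatives were a −log10 q of at least 5, an equal number of peaks per library (the top 54771 by −log10 p), a fold of at least 4, summits within 200 bp of each other chained into regions, leaving out each library in turn, and a block by replicate number. Gene lists and motif searches planned before the data were examined were not run, since the annotation at hand is of the GRCm38 build and the coordinates are mm9. As a check of the build, 18.97% of 21900 protein-coding genes had a peak of the WT 0 h replicate 1 library within 1000 bp of either end, and 16.55% did after a shift of 50 kb. No gene is named for a region for that reason. The position of the lincRNA-EPS gene in mm9 was not used here, so the deletion could not be looked up by position. The planned check of the genotype labels expected the deleted locus among the regions called in every WT and no KO library. Of the regions that separate the genotypes, 0 lie on chromosome 4, which carries the gene, so the labels gained no such support. A deleted locus without a peak in every WT library would give the same result, so the check decides nothing.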

Results

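Accessible chromatin was mapped in macrophages from WT and lincRNA-EPS KO mice before LPS and after 2 and 6 h of LPS. The study's title casts this noncoding RNA as a restraint on inflammatory transcription, and the design asks how LPS changes open chromatin and whether its loss alters that. The 12 libraries gave 54771 to 91610 peaks each. The shallowest library was KO 0 h replicate 2, with a background coverage of 1.43 reads, which was 42.6% of that of the deepest, KO 6 h replicate 1, at 3.35. The other KO library at 0 h had 1.77, and the WT libraries at 0 h had 2.35 and 2.51. Of the 115231 regions, 42811 (37.2%) were called in all 12 libraries and 17958 (15.6%) in 1 library. All coordinates are mm9, and gene annotation of that build was not used here.

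The number of called peaks per library was higher at the later times of LPS. Libraries at 0 h held 63572.5 ± 5911 peaks, those at 2 h 73640 ± 2825, and those at 6 h 84323.5 ± 5517 (mean ± SD, n = 4 libraries each). The peaks covered 32.3 ± 3.30 Mb at 0 h, 38.9 ± 1.92 Mb at 2 h and 43.2 ± 3.60 Mb at 6 h. The rise of 20751 peaks from 0 to 6 h had an exact permutation p = 0.00025, the smallest this design can give. It was present in WT, from 67006.5 ± 172 to 83459 ± 2418 peaks (n = 2 each), where mean background coverage was 2.43 at both times. In lists thinned to the background coverage of the shallowest library the rise was 15445 peaks, with the same exact p = 0.00025.

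**Figure D1:**
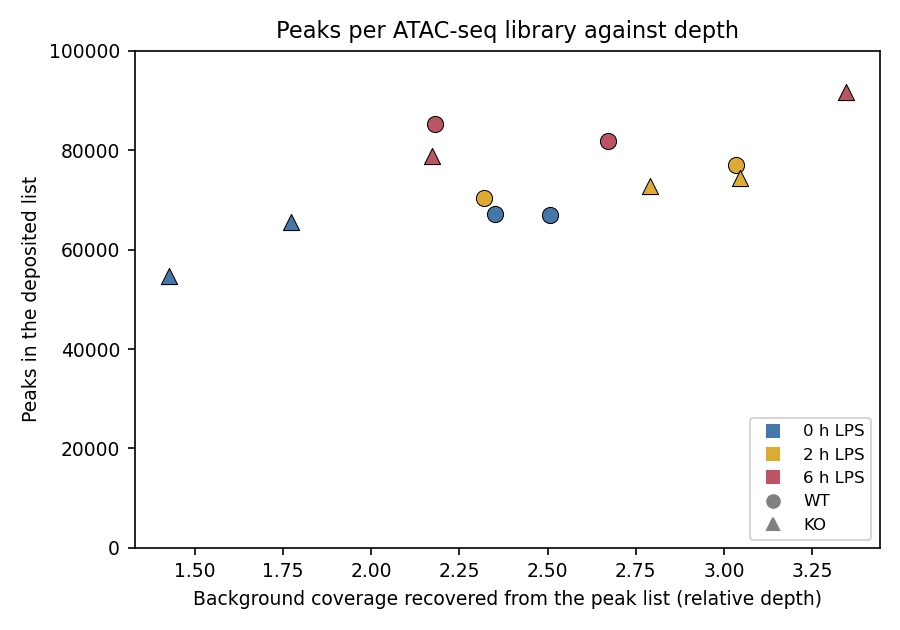
Number of peaks in each of the 12 libraries (vertical axis) against background coverage in reads, a measure of relative depth (horizontal axis), with time by colour and genotype by symbol. The libraries at 6 h hold 78766 to 91610 peaks and all lie above those at 0 h, which hold 54771 to 67128, while the KO libraries at 0 h are also the shallowest.

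By 6 h of LPS, 6389 regions had been gained in all 4 libraries and 146 had been lost. The strongest gained region lay on chromosome 18 at 11886284 to 11887067. Its peaks stood at the 97.3 percentile ± 1.0 of −log10 q in the libraries at 6 h, with a mean fold of 14.9 ± 0.26 (SD, n = 4), and it was called in 0 of 4 libraries at 2 h. Chromosome 17 held the next, at 17591364 to 17592120, with a mean percentile of 96.6 ± 1.3 and a fold of 14.04 ± 0.90, and a further region at 87349286 to 87350131, at 95.4 ± 0.79. Both were already called in all 4 libraries at 2 h. A region on chromosome 14 at 58102863 to 58103499 had a mean percentile of 95.8 ± 0.69 and the highest mean fold of the 5 named, 15.7 ± 1.1. It was called at 2 h in both KO and in 0 of 2 WT libraries. The last of the 5, on chromosome 13 at 111423403 to 111424326, had a mean percentile of 94.4 ± 1.5.

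The highest-ranked region lost by 6 h, on chromosome 4 at 19765147 to 19765830, had a mean percentile of 59.2 ± 11.4 and a fold of 9.06 ± 1.4 at 0 h (SD, n = 4). The next were on chromosome 3 at 79493570 to 79494725, at 51.3 ± 11.2, and on chromosome 19 at 58428383 to 58428909, at 48.3 ± 11. Regions on chromosome 6 at 86569934 to 86570465 and on chromosome 3 at 126353176 to 126353776 stood at 45.7 ± 18.4 and 45.6 ± 7.1. All 5 were still called in all 4 libraries at 2 h. The median width was 486 bp for gained regions, 451 bp for lost regions and 775 bp for regions called in all 12 libraries. Percentiles at 0 h and 6 h come from lists of different lengths and are not compared.

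Among the 68 other ordered splits of the 8 libraries at 0 and 6 h, the highest count was 334 regions and the mean 58.3. The 6389 gained regions exceeded all of these, and the 146 lost regions were matched by 8. Those 8 hold 3 libraries of a time on the same side, and among the 36 splits with 2 libraries of each time on both sides the highest count was 130. Thinned lists gave 4799 gained and 225 lost regions, with 1 of the 68 other splits as high as the lost count and 88 the highest of the 36. The lost count was 389 without KO 0 h replicate 2 and 283 without KO 6 h replicate 1. Gained regions made up 97.8% of those that changed in the deposited lists and 71.1% with an equal number of peaks per library, a setting in which each added peak displaces another.

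The response at 2 h was smaller, with 909 regions gained and 5 lost. The strongest gained region, on chromosome 3 at 135302981 to 135303722, had a mean percentile of 68.0 ± 8.3 and a fold of 8.44 ± 0.74 (SD, n = 4). It was followed by regions on chromosome 10 at 117303804 to 117304953, with 63.4 ± 7.1, and on chromosome 1 at 137711807 to 137712509, with 60.7 ± 11. Regions on chromosome 8 at 70770571 to 70771383 and on chromosome 1 at 182167425 to 182168168 stood at 57.6 ± 9.0 and 57.4 ± 6.2. All 5 were also called in all 4 libraries at 6 h. The 5 lost regions lay on chromosome 6 at 136432543 to 136433025, chromosome 2 at 17564498 to 17564911, chromosome 9 at 114284466 to 114284867, chromosome X at 150104830 to 150105180 and chromosome 19 at 6373768 to 6374250. Their mean percentiles were 12.2 to 22.9.

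Other splits of the 8 libraries at 0 and 2 h reached 274 regions, below the 909 gained, and all 68 gave at least the 5 lost. Thinning left 516 gained and 21 lost regions. The share of gained among changed regions was 99.5% in the deposited lists and 84.6% with an equal number of peaks per library. Without WT 0 h replicate 1, WT 0 h replicate 2 or WT 2 h replicate 2, the gained count was 1412, 1420 or 1472, and the lost count ran from 9 to 64 with any of the 8 libraries left out.

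Gains accumulated over time. Of the 909 regions gained by 2 h, 540 were called in all 4 libraries at 6 h and 57 in 0 of 4. Of the 6389 gained by 6 h, 3349 were called in 0 of 4 libraries at 2 h and 540 in all 4. Of the 146 lost by 6 h, 90 were still called in all 4 libraries at 2 h and 0 were absent from all 4. No region was called in all libraries at 0 h, 0 of 4 at 2 h and all at 6 h. Thinned lists held 4 such regions, and 2677 of the kind called at 6 h alone.

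**Figure D2:**
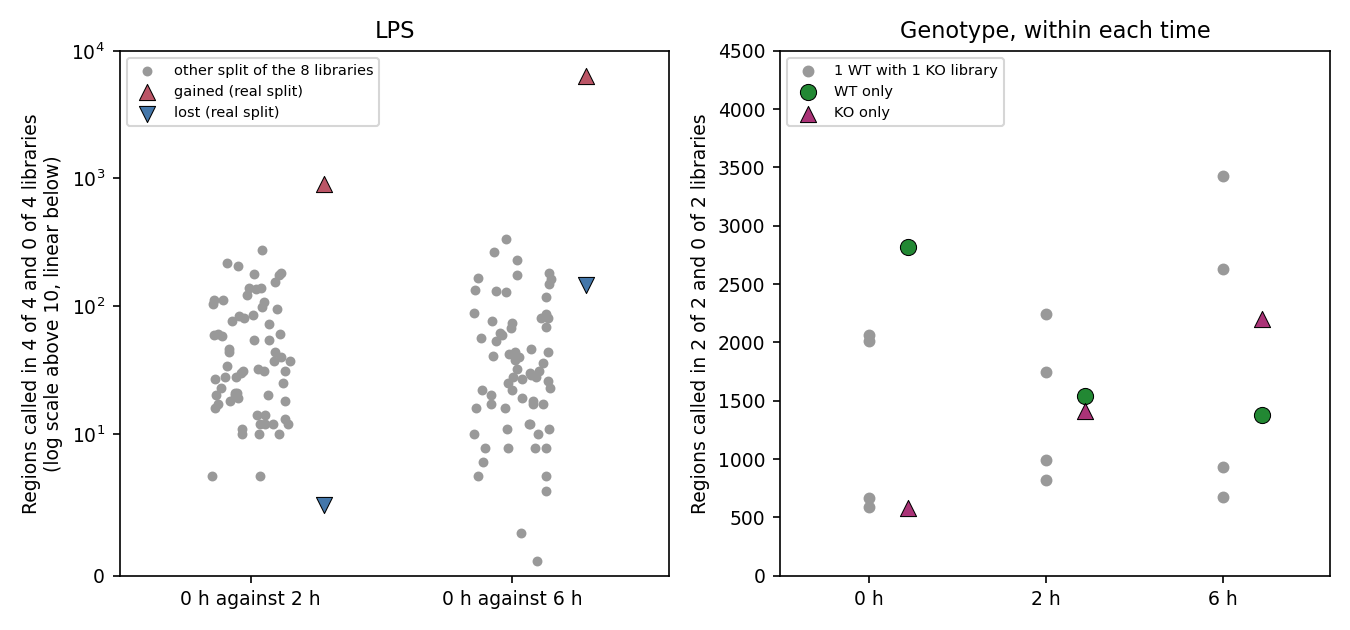
Left, regions called in all 4 libraries of one side and 0 of 4 of the other, for gained and lost regions and for every other split of the same 8 libraries (grey), on a log axis that is linear below 10. Right, regions called in both libraries of one genotype and in neither of the other at each time, beside pairs made of 1 WT and 1 KO library (grey); the 6389 regions gained by 6 h lie above the highest other split at 334, while the genotype counts at 2 and 6 h lie within the range of the mixed pairs and at 0 h the 2821 WT-only regions lie above it and the 582 KO-only regions below it (591 to 2061).

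The peak lists of WT and KO were nearly as alike as those of replicates. A library shared 86.5% ± 1.25 of its peaks with its replicate (SD over 6 pairs) and 86.3% ± 1.17 with libraries of the other genotype at the same time (12 pairs). It shared 82.0% ± 2.75 with libraries of its own genotype at other times (24 pairs). Among these, pairs of 0 h with 2 h shared 85.8% to 86.5% in WT and 82.2% to 85.3% in KO. Pairs that include 6 h shared 76.4% to 82.1%. In WT the measure thus hardly told 0 h from 2 h, so it may also miss genotype differences of that size. The pairs share libraries, so no test was made. The difference of KO minus WT in peak number was −1782, with an exact permutation p = 0.565, so no genotype difference was detected (n = 6 libraries each). In thinned lists it was −1803.5, with an exact permutation p = 0.380.

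Across all 3 times, 12 regions separated the genotypes, 10 called in WT only and 2 in KO only. The strongest lay on chromosome 5 at 110425056 to 110426057. All 6 WT libraries called it, at a mean percentile of 91.8 ± 1.6 and a fold of 12.6 ± 1.3 (SD, n = 6), and 0 of 6 KO libraries did. A region on chromosome 6 at 144865533 to 144866152 was also WT only, at 81.3 ± 3.8 and a fold of 12 ± 0.97. Further WT-only regions lay on chromosome 8 at 115450629 to 115451309, on chromosome 6 at 3376876 to 3377538, on chromosome 13 at 88802257 to 88802753 and on chromosome 8 at 126156943 to 126157297, with mean percentiles of 32.3 to 51.9. The remaining 4 stood lower, at 13.5 to 31.5. They were chromosome 14 at 70041657 to 70042432 and at 70079032 to 70079442, chromosome 18 at 60765686 to 60766071 and chromosome 19 at 45298580 to 45298939. The KO-only regions were on chromosome X at 166438916 to 166439375, with a mean percentile of 47.9 ± 6.5, and on chromosome 10 at 5989573 to 5990314, at 13.1 ± 12.6.

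Of 100 splits of the 12 libraries into 6 and 6, the real one included, 10 separated at least 12 regions. Thinned lists kept the KO-only count at 2 and gave 6 WT-only regions. Leaving out KO 0 h replicate 2 gave 10 KO-only regions, leaving out WT 0 h replicate 1 gave 4, and WT-only regions numbered 16 without WT 0 h replicate 2 or WT 6 h replicate 2 and 18 without KO 6 h replicate 1.

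**Figure D3:**
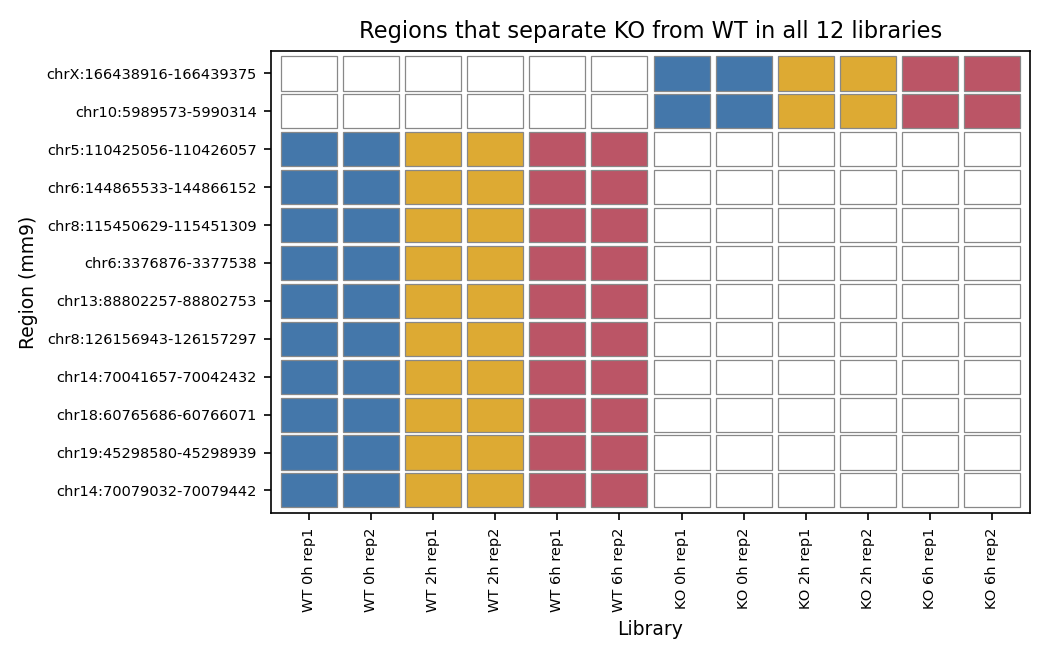
The 12 regions that separate the genotypes (rows, mm9 coordinates) in the 12 libraries (columns), where a filled square marks a called peak, coloured by time, and an empty square none. The 10 WT-only regions are called in 6 of 6 WT libraries and the 2 KO-only regions in 6 of 6 KO libraries.

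At rest, 2821 regions were called in WT only and 582 in KO only. The WT-only regions on chromosomes 5 and 6 at 110425056 and 144865533 led that list. They were followed by chromosome 16 at 76149489 to 76150346, with a mean percentile of 59.6 ± 6.1 (SD, n = 2), chromosome X at 90847224 to 90848052, with 56.2 ± 2.3, and chromosome 9 at 15745389 to 15745818, with 54.5 ± 11.1. KO libraries called the first 2 of these 3 in all 4 libraries with LPS. The KO-only list at rest was led by chromosome 3 at 148165921 to 148166424, with 53.7 ± 0.62, and chromosome 17 at 89418848 to 89419350, with 47.5 ± 0.012. The X chromosome region at 166438916 came next. The last of the 5 were chromosome 10 at 98559971 to 98560470 and chromosome 2 at 73397741 to 73398128, with 42.6 ± 1.8 and 42.3 ± 14.2. With LPS, 3 WT libraries called the chromosome 3 region, 2 the chromosome 17, 3 the chromosome 10 and 4 the chromosome 2 region. The X chromosome region was called in 0 WT libraries.

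The WT excess at rest changed with the setting. WT-only regions made up 82.9% of the separated regions in the deposited lists, 67.8% in thinned lists and 54.9% with an equal number of peaks per library. KO 0 h replicate 2 had the fewest peaks at rest in the thinned lists too, 54770 against 61527 to 64200 in the others. With 1 WT library set against 1 KO library, a comparison chosen after the data were examined, KO 0 h replicate 2 gave WT-only shares of 82.1% and 81.1%, and KO 0 h replicate 1 gave 55.4% and 54.4%. In thinned lists these were 74.3% and 70.1%, and 48.3% and 43.7%. KO-only and WT-only counts were 4694 and 4307 without KO 0 h replicate 2, 1859 and 8901 without KO 0 h replicate 1, 1627 and 7239 without WT 0 h replicate 1, and 1520 and 7349 without WT 0 h replicate 2. A lone library then needs 1 call where the pair needs 2, so the sides of such counts are not compared.

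With LPS, WT-only and KO-only regions numbered 1539 and 1411 at 2 h and 1380 and 2198 at 6 h. The totals were 2950 and 3578, and the mixed pairings gave 2742 and 3062 at 2 h and 3560 and 4101 at 6 h. At rest the total was 3403, against 2652 and 2681. In thinned lists the total at rest was 2876, against 2899 and 2739. At 2 h the thinned total was 3194, above both mixed pairings at 2793 and 2937. At 6 h it was 3748, between the mixed pairings at 3565 and 3865. The WT-only share at 6 h was 38.6% in the deposited lists, 51.4% in thinned lists and 49.1% with an equal number of peaks per library. With 1 WT library against 1 KO library, the WT-only share ran from 38.2% to 63.9% at 2 h and from 28.7% to 64.9% at 6 h, so the direction varied with the libraries chosen at both times. In thinned lists the 1951 WT-only regions at rest lay within the range of the mixed pairs, 644 to 2255, and the 1909 at 2 h lay above theirs, 1234 to 1559. The WT-only share of 1 library against 1 ran in these lists from 53.0% to 58.7% at 2 h and from 38.5% to 64.2% at 6 h.

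The regions gained by 6 h in WT and in KO overlapped. WT gained 11399 regions and KO 14353 (2 of 2 libraries at 6 h, 0 of 2 at 0 h), of which 6389 were shared. Shared regions were 56.0% of the WT gains and 44.5% of the KO gains. A region outside the shared set need not be gained in 1 genotype alone, since it may miss the rule by 1 library. The change was absent in KO for 915 of the WT gains and absent in WT for 1580 of the KO gains. In 34 other arrangements of the same libraries such counts ran from 456 to 2434, with a mean of 1270. Of the 30783 regions called in 0 of 4 libraries at 0 h, which could be gained in both genotypes, WT gained 9295 and KO 9924, and independent lists would share 2997. Of lost regions, 1686 in WT and 575 in KO, 146 were shared. Of the 45944 regions called in all 4 libraries at 0 h, WT lost 423 and KO 307, and independent lists would share 2.83. Regions differ in how easily they are called, which raises such overlaps by itself. In thinned lists WT gained 9851 and KO 10702 regions, and WT lost 1733 and KO 1198. The change in peak number from 0 to 6 h was larger in KO by 8597 peaks, with an exact permutation p = 0.389, and by 2283.5 in thinned lists, with p = 0.778. The smallest p this test can give is 0.0556, so a genotype difference in the LPS change could not have passed the threshold.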

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

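The tests on random splits of all 12 libraries, library enrichment, the 6 deepest libraries and the rank of separated peaks were set before their results were seen. The tests on splits by time, on thinning, on 1 library against 1, on time-balanced splits, on neighbouring regions and on the chromosome of the gene were chosen after the results were seen.

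A difference in direction between genotypes appeared at 85 regions. By 6 h, 11 regions were gained in both WT libraries and lost in both KO libraries, and 74 were lost in both WT and gained in both KO libraries. In thinned lists the counts were 25 and 40. The difference was not tested for any region. In 17 other arrangements of the same libraries the total was 42 to 138, with a mean of 71.8, and 4 of them gave at least 85.

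The gain of 6389 regions by 6 h was weighed against chance, depth and library quality. Of 35 splits of the 8 libraries, 1, the real one, gave as many changed regions (6535, against 341 in the highest other), and at 2 h likewise 1 of 35 (914, against 284). That is the smallest share 35 splits can give, so it argues against a chance division of the libraries without excluding it. Depth alone would remove the gains, yet 4799 were gained in thinned lists and 4760 to 4914 over 20 random thinnings. Better enriched libraries at 6 h would raise summit coverage over background at regions called in all 12 libraries, but the ratio of 6 h to 0 h there was 0.938. That ratio cannot exclude enrichment, because the measure was 10.17 in the shallowest and 8.76 in the deepest library. Mean background coverage was 2.01 at 0 h and 2.59 at 6 h. In WT, where it was 2.43 at both times, the measure was 9.43 ± 0.27 at 0 h and 9.36 ± 0.61 at 6 h (SD, n = 2), so no rise was seen there. These values argue against chance and depth as the whole cause. An LPS effect on chromatin remains a hypothesis, since other differences between the libraries of the 2 times were not tested.

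The excess of WT-only regions at rest may come in part from sequencing depth, since the KO libraries at 0 h were the shallowest. Thinning lowered the WT-only share from 82.9% to 67.837%. Mixed pairings of these 4 libraries decide nothing, because KO 0 h replicate 2, with the fewest peaks before and after thinning, stands in each of them. With 1 WT against 1 KO library in thinned lists, that library gave WT-only shares of 74.3% and 70.1% and KO 0 h replicate 1 gave 48.3% and 43.7%, so the excess rests on it. Depth, another property of that library and a genotype effect at rest cannot be told apart with 2 libraries per group.

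The 12 regions that separate KO from WT were not beyond chance in the planned test, since 10 of 100 splits gave at least as many (highest other 193), but the others that did so divide the times unevenly. Among 100 splits with 2 libraries of each time on both sides 1, the real one, reached 12 (highest other 10), although under the looser rule of at least 5 against at most 1 library 14 of the 99 others reached the real 265. The 6 deepest against the 6 shallowest libraries separated 3 regions. That split has 3 KO libraries on the deeper side, so it crosses the genotypes and cannot show how depth affects their separation. Thinned lists gave 2 KO-only and 6 WT-only regions, and time-balanced splits were not run on them. The highest mean percentile of any region separated by the other time-balanced splits was 32.364. This argues against calls near the limit for the regions on chromosomes 5 and 6, picked after their percentiles of 91.8 and 81.3 were seen. A sequence difference linked to the knockout allele does not account for these 12, since 0 of them lie on chromosome 4, which carries the lincRNA-EPS gene, but it stays open for a chromosome 4 region at 109073844, called in 5 of 6 KO and 0 of 6 WT libraries. A sequence or copy difference elsewhere between the mouse lines may explain some. Of the 12, 2, the chromosome 14 pair, lay within 100 kb of each other (one-sided permutation p = 0.009 over 1000 random draws, mean 0.016). Of the 265, 21 had such a neighbour (permutation p = 0.008, mean 10.7). The explanation predicted more neighbours than random draws give, and this was met. A further demand, that at least 6 of the 12 have such a neighbour, was added after this value was seen and was not met. The explanation stays open, as does an effect of the RNA itself.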

How the results depend on the processing

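Thinning was chosen after the data were examined; the other settings were set before. The rise in peaks with LPS kept its direction and passed its test in all settings run, 17817 to 22604 peaks with a library left out, and KO minus WT passed in none, −3923 to 358.5. Replicate numbers did not pair libraries (correlations of −0.013 to 0.024 over 15 pairs of groups), and with the replicate block the exact permutation p was 0.00154 for the LPS change of 20751 and 0.594 for the KO difference of −1782.

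An equal number of peaks per library gave 303 gained and 55 lost regions by 2 h, 2706 gained (also those shared by WT and KO) and 1100 lost by 6 h, 4 regions in every KO library and no WT library, 1138 KO-only and 1386 WT-only at 0 h, 1244 KO-only at 6 h and a replicate similarity of 88.1%. By construction each added peak displaces another there. A fold of at least 4 gave 565 and 38 by 2 h, 367 lost by 6 h and 1 in every KO library. Thinning gave 516 and 21 by 2 h, 225 lost by 6 h, 6 in every WT library and 925 KO-only at 0 h. Chained summits gave 37 lost by 2 h and 245 by 6 h, a −log10 q of at least 5 left 1 in every KO library, a rule of at least 5 against at most 1 library gave 80 in KO and 185 in WT, and an overlap of 50% lowered the similarity to 81.9%. The cause was not tested for these.

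Leaving out a library loosens the rule by construction. Counts were then 1068 to 1472 gained and 9 to 64 lost by 2 h, 6736 to 8079 gained (and shared) and 181 to 389 lost by 6 h, 2 to 10 in every KO library and 11 to 18 in every WT library. Within times they were 1520 to 4694 KO-only and 4307 to 8901 WT-only at 0 h, 2680 to 5333 and 3460 to 7007 at 2 h, and 4435 to 9678 and 2246 to 6180 at 6 h. The highest lost counts, 64 and 389, came without KO 0 h replicate 2, the shallowest library, and without KO 6 h replicate 1 there were 283 lost by 6 h. The planned gene list and motif alternatives were not run. Low depth may limit calls of weak regions, and background coverage was lowest in KO at 0 h.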

Other observations

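The tests of calls at 2 h and of resting KO libraries were set before their results were seen, and the tests of clusters and of runs without a KO call and the places named here were chosen after.

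Regions gained by 6 h lay near each other. Of 6389, 1691 (26.5%) had another gained region within 20 kb, against a mean of 1245 (19.5%) and a highest of 1349 in 1000 random draws of regions not called in all 12 libraries (one-sided permutation p = 0.001, the smallest the draws can give). Windows of 200 kb with the most gained regions were on chromosome 13 from 42200001 and from 16000001, with 9 each. The window on chromosome 13 from 16000001 held 22 regions in all, of which 1 was called in all 12 libraries. Windows on chromosome 10 from 18800001 and from 96800001, chromosome 16 from 84600001 and chromosome 3 from 135200001 held 8 each, and the last contains the strongest region gained by 2 h. LPS may open stretches of chromatin together, though a draw that ignores the local density of regions may explain part of the excess.

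A faster response in KO was tested on the regions gained by 6 h. In thinned lists, KO libraries at 2 h called 24.5% and 22.6% of them, and WT libraries 20.9% and 22.005%. The lowest KO library lay 0.604 points above the highest WT library, and both KO libraries lay above both WT libraries in 19 of 20 random thinnings. Over these thinnings the mean was 23.6% in KO and 21.4% in WT, with a pooled SD between replicates of 1.108. In the deposited lists the KO libraries called 27.2% and 28.3%, and the WT libraries 26.7% and 21.6%. The order that a faster response requires was there, but 2 against 2 libraries give no exact permutation p under 0.333, so the hypothesis stays open. A condition added after the values were seen, that the gap of 0.604 exceed the pooled SD, was not met.

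A second hypothesis was that KO macrophages at rest already have LPS-response regions open. Regions absent from 1 WT library at 0 h and gained in WT by 6 h were looked up in the other WT library and in both KO libraries at 0 h, in thinned lists. The KO libraries called 27.3% and 16.5%, against 23.4% in the held-out WT library, and with the WT libraries exchanged 29.5% and 18.5%, against 28.4%. The KO mean lay −2.921 points from the held-out WT library over both choices, and the KO libraries lay on both sides of it, so the test decided nothing.

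A pair of stretches held WT peaks and no KO peak. On chromosome 8 from 115389656 to 115620664 (231 kb), 11 neighbouring regions had 25 calls in the 6 WT libraries and 0 in KO. On chromosome 14 from 70041657 to 70090466 (48.8 kb), 10 regions had 23 and 0. These runs include 3 of the regions that separate the genotypes, and 6 and 5 of their regions were called in 1 library alone. The calls were uneven, 1 to 9 per WT library on chromosome 8 and 2 to 7 on chromosome 14. Among 100 splits with 2 libraries of each time on both sides, 1, the real one, held a run with as many as 25 calls, and the highest other reached 14. In several of the other splits that run of 14 lay within the same chromosome 8 stretch, and in others on chromosomes 11 and 1. A deletion or other sequence difference in the KO line may lie in these stretches, as may lower accessibility, and peak lists without reads do not separate these.

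Near the end of the X chromosome, calls differed by genotype at neighbouring regions. At 166433300 to 166434126, 5 of 6 WT and 0 of 6 KO libraries had a peak, with a mean fold of 1.9 where called. At 166437174 to 166437561, 0 WT and 5 KO libraries had a peak, next to the KO-only region at 166438916, with mean folds of 3.5 and 4.0. The region between the WT and KO calls, at 166434760 to 166436475, was called in all 12 at a mean fold of 4.8. These KO calls formed the KO-only run with the most calls, 11 in 2 regions. Runs in other time-balanced splits reached 14, so this run was not beyond them. The cause was not tested. On chromosome 4 at 109073844 to 109074543, 5 of 6 KO and 0 of 6 WT libraries had a peak, and the missing KO library was the shallowest, KO 0 h replicate 2. This is the chromosome of the lincRNA-EPS gene, but the position of the gene in mm9 was not used here.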
